A study of Rattus norvegicus with 24 samples.

How the data were processed

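Small RNA was sequenced from the serum of male Wistar Kyoto rats in 4 groups that crossed diet (normal, or 6% fish oil by weight) with exposure (filtered air, or 0.8 ppm ozone). No diet with another oil was analysed here, so a fish oil effect below is a difference from the normal diet. Fish oil itself cannot be told apart from added oil in general or from any other difference between these diets. Per the labels, RNA was taken from 100 µl of serum with a biofluids column kit that included a DNase step, 10 ng of RNA entered a small RNA library kit, and the libraries were read for 50 cycles from 1 end. The labels describe 24 samples, 6 per group. Tables with 23 libraries were used here, and fish oil ozone replicate 2 was not analysed here, which leaves 5 libraries in that group. Every library was joined to its group through the animal number, which is in both its sample title and its table column name. Animal numbers run in separate blocks for each group, so they pair no rats, no block term could be fitted, and a batch that followed those blocks could not be told apart from the groups.

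The deposited table of expected counts gives the reads of each mature miRNA locus in each library. Its values were read as estimates because 50 of its 832 loci hold fractions. How reads that match several loci or names were handled is not stated. Per the submitters' processing notes, bcl2fastq, Partek and Bowtie 1.0.0 were used with the rat genome build rn5; the order of the steps, the annotation and any filters are not given in the sources used here. The other table that the authors deposited holds RPM, reads scaled to 1 total per library. In each library its values equal the counts summed over loci, divided by that total, plus an offset of 0.0001, and they match this to within 0.0401 reads. The total is not stated; worked out from both tables, it lay between 2243920 and 7729940 reads per library, far above the miRNA counts, and it is called the implied read total below. Positions are given as the files give them, on rn5; the files do not say whether they count from 0 or from 1.

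Loci of 1 miRNA were summed (753 names, with several loci for 17 of the 136 tested below) and rounded to whole counts. The miRNA total lay between 23279 and 94264 counts per library. A count of 3, taken as the lowest that can be told from 0, is 31.8 to 129 CPM across libraries; such floors cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. A count was seen for 454 names, and 136 passed the low-count filter of edgeR (filterByExpr by group, minimum count 10, minimum total 15). These 136 hold 99.3% of the counts. Some names share reads. The mature miR-210-3p and miR-3574 have identical counts, let-7a-5p and miR-3596a have identical counts at 1 shared locus, and the locus named miR-3557-5p takes reads of miR-378a-3p, so values of these are uncertain.

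Counts were scaled by the trimmed mean of M values (TMM) and tested with the edgeR 4.0.16 quasi-likelihood F test (robust, two-sided, 1 mean per group) in R 4.3.3. There were 7 contrasts: ozone on each diet, fish oil under each exposure, their interaction, ozone averaged over diets and fish oil averaged over exposures. The p-values were adjusted by Benjamini-Hochberg over the 136 miRNAs of each contrast, with a threshold of 0.05; rose, fell and changed are used below only for results past it. Standard errors (SE) of log2 fold changes come from the same fits. From the means of the normal diet air libraries and the spread of all libraries, simulated counts with known changes gave the share recovered by edgeR over 20 draws of 136 miRNAs. The changes went up or down at random, and the miRNAs were drawn independently. These shares therefore do not cover miRNAs that move together or a shift of most miRNAs in 1 direction. For fish oil averaged over exposures, 41.5% of 1.5-fold changes, 81% of 2-fold changes and 99% of 4-fold changes were called, with 1.35% of unchanged miRNAs. For fish oil under air, 23% of 1.5-fold changes, 58% of 2-fold changes and 93.5% of 4-fold changes were called.

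The 15 lists of miRNAs were written before the data were examined. They cover tissues and cells (erythrocyte, liver, striated muscle, vascular wall, epithelium, myeloid inflammation, lymphocyte, platelet, neural and neuroendocrine), processes (lipid metabolism, oxidative and hypoxic stress), families and clusters (let-7, miR-30, miR-17-92 and its paralogs, Dlk1-Dio3). Lists with 3 or more tested members were compared with all other miRNAs by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists; an estimated correlation was run beside it, as was fry, which asks only whether the members of a list move one way and compares them with no other miRNAs. In 20 simulated draws camera called a list of 8 random miRNAs raised 1.5-fold 20 times and an unchanged list 0 times, at an unadjusted p below 0.05. The miRNAs were drawn independently there, so these draws do not test the preset correlation for lists whose members move together. Library totals, the number of miRNAs with 5 or more counts, the percent of counts taken by miR-143-3p (the miRNA with the highest mean share over all libraries, though not the highest in every one), the miRNA share of the implied read total, and an erythrocyte index were compared by two-sided exact permutation tests between pairs of groups, adjusted over 4 comparisons. Averages over strata used permutation tests within strata with 100000 resamples. Library totals, the implied read total and the miRNA share were compared on the log2 scale, so their ratios are ratios of geometric means. The erythrocyte index is log2 CPM of miR-451-5p minus that of miR-23a-3p, a usual measure of haemolysis in serum. MiR-451-5p had a mean count of only 29.4 per library and lay below miR-23a-3p in every library, so the index rests on few reads.

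The comparisons, the tests, the lists and the rule for naming miRNAs were also fixed before the data were examined, as were most alternatives. The rule names, for each simple or averaged effect, up to 12 miRNAs per direction with the smallest p among those past the threshold; with fewer than 5 past it, the 5 smallest p as values only; for the interaction, the 5 smallest p. It adds up to 4 most abundant members of each list and any member past the threshold, miR-451-5p, miR-23a-3p and the 5 most abundant miRNAs. Comparison of the miRNA share of the implied read total was added after the data were seen.

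Alternatives were other scalings (RLE factors of edgeR, total count), no low-count filter or a filter of 10 CPM in 6 libraries, DESeq2 1.42.0, limma voom with quality weights, only the groups compared, the erythrocyte index as a covariate, limma on the authors' RPM values with 1 added before log2, and leaving out each library. Those added after seeing the data were the implied read total as library size, libraries thinned to the smallest total for the tests of single miRNAs, library size without the 5 most abundant miRNAs, the share of whichever miRNA was most abundant in each library, and leaving out a pair of fish oil libraries that stood apart on principal components. Thinning for the number of miRNAs detected was fixed before. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.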

Results

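Serum miRNAs were counted in 23 libraries, 1 per rat: 6 on the normal diet in air, 6 on the normal diet in ozone, 6 on fish oil in air and 5 on fish oil in ozone. The diets began at 4 weeks of age and lasted 8 weeks; air or ozone (0.8045 ppm as measured) was then given for 4 h on each of 2 days. Libraries are named here by group and replicate, so that fish oil ozone 3 is replicate 3 of the rats on fish oil exposed to ozone. The serum held mainly a few abundant miRNAs: the 5 most abundant took 50.5% of the counts on average. Levels are CPM after TMM scaling, given as mean ± SD.

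Rats on fish oil gave fewer miRNA reads, and a larger part of those reads came from miR-143-3p, a miRNA of smooth muscle and other mesenchymal cells. The miRNA total was 65638 ± 15674 counts on the normal diet in air and 63357 ± 20129 in ozone (SD, n = 6 each). On fish oil it was 37264 ± 11332 in air (n = 6) and 33302 ± 7385 in ozone (n = 5). By geometric means, fish oil rats had 0.558 times the normal diet total in air (exact permutation test, p = 0.00433, adjusted p = 0.0173) and 0.541 times in ozone (exact p = 0.0130, adjusted p = 0.026). Without fish oil ozone 3 or without fish oil ozone 6 the comparison in ozone had an adjusted p of 0.0571. The share of miR-143-3p was 12.4 ± 4.90% and 11.8 ± 2.85% on the normal diet in air and ozone, against 25.1 ± 8.29% and 28.2 ± 5.50% on fish oil. It was 12.7 points higher under air (exact p = 0.0152, adjusted p = 0.0303) and 16.4 points higher under ozone (exact p = 0.00216, adjusted p = 0.00866). In all 12 normal diet libraries miR-191a-5p outnumbered it, so the share of whichever miRNA was most abundant in a library was 1.87 points higher on fish oil under air and 4.29 under ozone, neither past the threshold (exact permutation, adjusted p = 0.812 and 0.667). Under air the adjusted p of the miR-143-3p share rose above the threshold, to at most 0.0606, without normal air 5, normal air 6, fish oil air 1 or fish oil air 4.

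The authors' RPM values give a further measure, the miRNA counts as a percent of the implied read total. It was 1.36 ± 0.563% and 1.56 ± 0.578% on the normal diet in air and ozone, and 0.660 ± 0.181% and 0.826 ± 0.335% on fish oil. The ratio of fish oil to normal diet, by geometric means, was 0.496 in air (exact permutation p = 0.00216, adjusted p = 0.00866) and 0.523 in ozone (exact p = 0.039, adjusted p = 0.0779, and 0.0476 without fish oil ozone 3). Without the 5 most abundant miRNAs the share in air had a log2 difference of −0.92 and did not pass (exact permutation, adjusted p = 0.0519). The implied read total itself had a ratio of 1.08 averaged over exposures (permutation p = 0.642). MiR-451-5p and miR-23a-3p, whose log2 difference rises when red cells break, gave an erythrocyte index of −2.07 ± 0.51, −2.65 ± 0.94, −1.83 ± 0.62 and −2.11 ± 1.21 in the same order of groups, with no difference past the threshold (fish oil averaged over exposures +0.39, permutation p = 0.287). The number of miRNAs with 5 or more counts was 161.5 ± 17.7, 161.5 ± 19.2, 150 ± 12.2 and 140.6 ± 9.89, and fell by 16.2 on average with fish oil (permutation p = 0.0216); after thinning to equal totals it was 9.18 higher. Ozone changed none of these library measures on either diet in the exact tests.

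**Figure D1:**
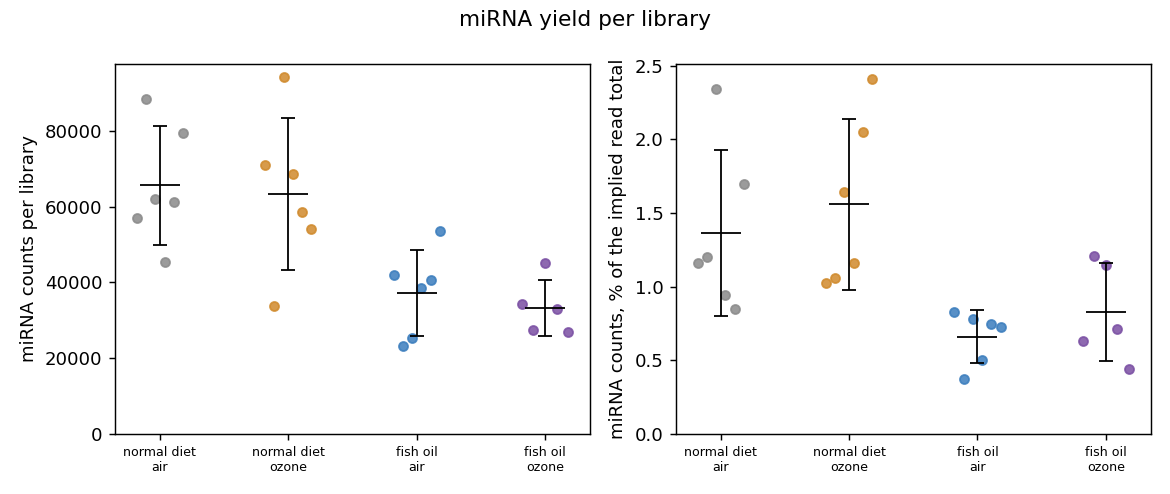
miRNA counts per library (left axis, counts) and miRNA counts as a percent of the implied read total (right panel, percent) in the 4 groups; points are libraries and bars are mean ± SD. Mean totals were 65638 and 63357 counts on the normal diet and 37264 and 33302 on fish oil.

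Averaged over air and ozone, fish oil changed 50 of the 136 miRNAs tested (edgeR quasi-likelihood, Benjamini-Hochberg), 27 higher and 23 lower. The smallest p was that of miR-191a-5p, which is plentiful in blood cells and platelets and fell by 1.54 on the log2 scale (SE 0.22, edgeR adjusted p = 8.04e-06, lower in 11 of 11 fish oil libraries). Its level was 254369 ± 64688 and 245408 ± 56261 CPM on the normal diet in air and ozone (n = 6 each), and 102649 ± 37464 and 71763 ± 36689 on fish oil (n = 6 and 5). MiR-128-3p, best known from brain and also a regulator of cholesterol export, fell by 1.18 (SE 0.19, edgeR adjusted p = 5.67e-05, lower in 11 of 11). MiR-199a-3p, a mesenchymal miRNA, rose by 1.20 (SE 0.21, edgeR adjusted p = 0.000115, higher in 10 of 11). MiR-143-3p rose by 1.06 (SE 0.23, edgeR adjusted p = 0.000944, higher in 9 of 11), from 137137 ± 67619 and 121985 ± 39823 CPM to 248187 ± 117500 and 294536 ± 104796.

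The loci of the named changes lie on several chromosomes (rn5), but some are neighbours. MiR-191a-5p lies on chromosome 8 at 116698881 to 116698904, next to miR-425-5p at 116699334 to 116699357, which also fell. MiR-181c-5p and miR-181d-5p, which both fell, lie together on 19 at 36267372 to 36267394 and 36267201 to 36267224. MiR-199a-3p lies on 13 at 85019466 to 85019488 and miR-143-3p on 18 at 56200210 to 56200232. MiR-128-3p lies on 13 at 50001755 to 50001776 and on 8 at 119718197 to 119718218. MiR-145-5p, transcribed together with miR-143 and lying next to it on chromosome 18 at 56198870 to 56198893, rose by 1.22 (SE 0.34, edgeR adjusted p = 0.00604, higher in 8 of 11). MiR-217-5p, enriched in the exocrine pancreas, rose by 3.14 (SE 0.64, edgeR adjusted p = 0.000703, higher in 9 of 11) from very few reads: its counts on the normal diet were 0 to 4 in all but 2 libraries, which had 7 and 31, and on fish oil they were 0 to 91. The other raised miRNAs with the smallest p were miR-152-3p (+1.15), miR-144-5p (+1.32), miR-30e-5p (+0.70), miR-497-5p (+1.29), miR-10b-5p (+1.40), miR-101a-3p (+0.90), miR-29c-3p (+1.09), miR-27b-3p (+0.61) and miR-30a-5p (+0.62). The other lowered ones were miR-181d-5p (−0.87), miR-328a-3p (−1.43), miR-181c-5p (−1.01), miR-92a-3p (−1.09), miR-425-5p (−0.75), let-7d-3p (−0.83), miR-146b-5p (−0.66), miR-151-3p (−0.65), miR-92b-3p (−0.97) and miR-326-3p (−1.58). Few reads were counted for miR-10b-5p, miR-144-5p and miR-326-3p, with mean counts of 8.48, 10.3 and 7.83 per library. MiR-326-3p fell below the low-count filter, and so was not tested, without normal air 3, normal ozone 1, normal ozone 4 or normal ozone 5. DESeq2 called 59 miRNAs and voom 58.

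The direction of many of these differences depends on what the counts are scaled to. With the implied read total as library size, the median of all 136 miRNAs moved from +0.06 to −0.87 (1.82-fold lower on fish oil), and the calls became 1 higher and 70 lower. Of the 27 raised miRNAs, 14 were still positive on that scale, miR-199a-3p and miR-143-3p among them, 1 (miR-217-5p) was still called higher and 0 were called lower. All 23 lowered miRNAs were still called lower. With the authors' RPM values 1 was higher and 74 lower, and with total count scaling 29 were higher and 13 lower. Under air alone the median moved to −0.78 and under ozone alone to −0.96.

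**Figure D2:**
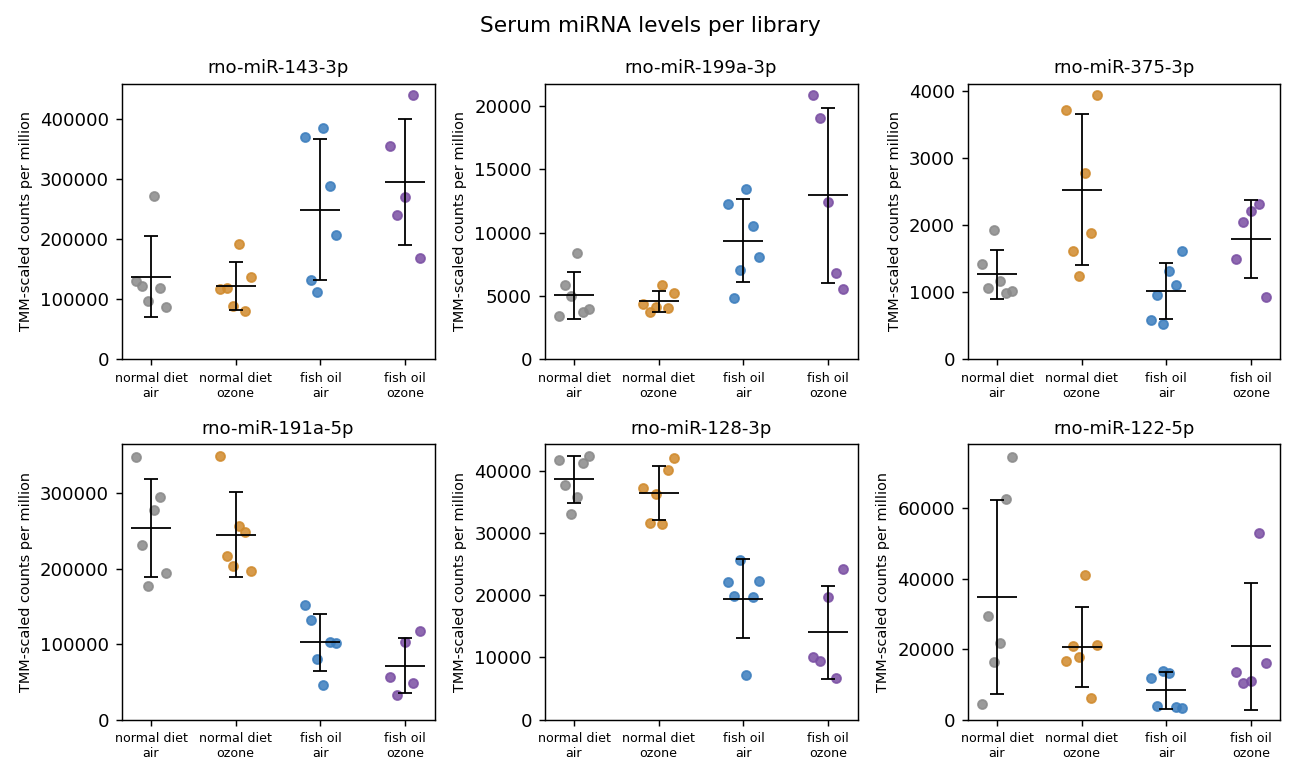
Levels of 6 miRNAs (CPM after TMM scaling) in the 4 groups; points are libraries and bars are mean ± SD. With this scaling miR-143-3p and miR-199a-3p were higher on fish oil, by 1.06 and 1.20 on the log2 scale averaged over exposures, and miR-191a-5p and miR-128-3p were lower, at −1.54 and −1.18.

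Among tissue and cell lists, miRNAs of the vascular wall lay higher relative to all others with fish oil averaged over exposures: 5 of the 6 tested rose over all miRNAs tested and 5 when adjusted over the list alone, with a median of +0.93 that became −0.09 with the implied read total (camera adjusted p = 0.0441). The adjusted p was 0.178 with an estimated correlation in camera, so the difference from other miRNAs did not pass there. The adjusted p in fry, which tests the list against no change and not against other miRNAs, was 0.000173. Its endothelial members miR-126a-3p (+1.06, SE 0.33, edgeR adjusted p = 0.0139, higher in 11 of 11) and miR-126a-5p (+0.64) rose with miR-143-3p, miR-145-5p and miR-221-3p (+0.45). MiR-126a-3p had few reads (mean count 11.3). Both miR-126a names lie side by side on chromosome 3 (from 9402781 and 9402744), and miR-143-3p lies next to miR-145-5p. The 5 of 6 are therefore not independent members. The call of the list ended without normal ozone 3 (camera adjusted p = 0.0614), normal ozone 5 (0.0597), fish oil air 5 (0.0507) or fish oil ozone 5 (0.0527), and with the erythrocyte index as a covariate (0.0515).

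No other list passed in camera for this average, though single members did. In the lymphocyte list 4 of 6 rose (4 adjusted over the list alone), among them miR-29a-3p (+0.68) and miR-181a-5p (+0.51), at a camera adjusted p of 0.0600. In the epithelium list miR-203a-3p (+0.72) and miR-205 (+1.18, SE 0.32, edgeR adjusted p = 0.00487) rose and 4 did not pass (camera adjusted p = 0.404). The miR-17-92 list had 3 lower and 7 not passed (0.244), and its member miR-92a-3p and the related miR-92b-3p, counted together, fell by 1.08 (edgeR adjusted p = 0.000702). In the liver list miR-192-5p fell by 0.62 (edgeR adjusted p = 0.0116) and miR-122-5p, the most liver-specific one, did not pass at −1.02 (edgeR adjusted p = 0.0668; list 0.394, with 2 lower adjusted over the list alone). Platelet miRNAs went both ways, with 2 higher, 4 lower and 4 not passed (0.414). The erythrocyte list had 2 higher and 3 lower of 9 (0.861), and its test pointed down although its median was +0.06. In the myeloid list miR-223-3p, a neutrophil miRNA, fell by 0.80 (edgeR adjusted p = 0.0164) and miR-146b-5p fell, against a positive list median of +0.16 and a test pointing down (0.769).

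Of the remaining lists, lipid metabolism had 1 higher, 3 lower and 8 not passed (camera adjusted p = 0.598), with a test pointing down and a median of +0.01. Oxidative and hypoxic stress had 3 higher and 6 not passed (0.347), with miR-144-3p at +0.98. In the neural list miR-218a-5p rose (+1.23, from few reads, with a mean count of 6.83 at its main locus), miR-128-3p fell and miR-375-3p did not pass (0.414). The miR-30 list had 2 higher of 6 (0.404), and its median of +0.27 became −0.62 with the implied read total. In the let-7 list only let-7g-5p fell (−0.45) and 8 did not pass (0.404). None of 3 striated muscle miRNAs passed (0.598), and none of the 28 Dlk1-Dio3 names reached the low-count filter, so that list was not tested.

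In filtered air, fish oil lowered miR-192-5p and miR-122-5p, which are 2 of the 3 liver miRNAs tested; the call of miR-122-5p depended on single libraries. MiR-192-5p, of liver and gut, fell by 1.08 (SE 0.26, edgeR adjusted p = 0.0120, lower in 6 of 6), from 92889 ± 25415 to 43977 ± 10120 CPM (n = 6 each). MiR-122-5p fell by 2.06 (SE 0.61, edgeR adjusted p = 0.0476, lower in 6 of 6), from 34874 ± 27651 to 8370 ± 5222 CPM. In all, 8 miRNAs changed, 1 higher and 7 lower, against 39 at an unadjusted p below 0.05. The raised one was miR-217-5p (+4.13, SE 0.95, edgeR adjusted p = 0.0120, higher in 5 of 6); miR-191a-5p (−1.31), miR-128-3p (−0.99), miR-425-5p (−0.87), miR-181c-5p (−0.98) and miR-328a-3p (−1.23) fell. DESeq2 called 7 higher and 8 lower, voom 17 and 14, total count scaling 11 and 3, library size without the 5 most abundant miRNAs 9 and 6, and the implied read total 1 and 37.

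The calls in air rest partly on single libraries. MiR-217-5p, miR-191a-5p and miR-192-5p were called in each fit that left out 1 library. With only the compared groups in the fit, 0 were called higher and 6 lower: miR-217-5p was left out by the low-count filter, and miR-122-5p did not pass (edgeR adjusted p = 0.0950). With limma on the authors' RPM, miR-217-5p had an adjusted p of 0.0510. MiR-122-5p was lost without normal air 2, 5 or 6, normal ozone 6, or fish oil air 2, 4, 5 or 6 (highest edgeR adjusted p = 0.102), and miR-328a-3p without normal air 1, 2, 5 or 6, normal ozone 4 or 5, or fish oil air 3, 4, 5 or 6 (highest 0.114). MiR-128-3p was lost without normal air 1, 5 or 6 or fish oil air 4, 5 or 6 (highest 0.0719), miR-181c-5p without normal air 5 or fish oil air 4, 5 or 6 (highest 0.0866), and miR-425-5p without fish oil air 4 or 5 (highest 0.0585). The number called was 3 without fish oil air 4 or 5, 4 without normal air 5 or fish oil air 6, 5 without normal air 6, and 15 without fish oil air 3.

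As lists under air, liver miRNAs lay lower relative to all others (camera adjusted p = 0.0375, 0.224 with an estimated correlation; median −1.08; 2 of 3 lower over all miRNAs tested and 3 adjusted over the list alone). Lymphocyte miRNAs lay higher with TMM scaling (camera adjusted p = 0.0375, 0.224 with an estimated correlation), with 0 of 6 higher over all miRNAs tested in edgeR, 3 adjusted over the list alone, and a median of +0.62 that became −0.30 with the implied read total. Vascular wall miRNAs lay higher with TMM scaling (camera adjusted p = 0.0457, 0.224 with an estimated correlation), with 0 of 6 passing either way and a median of +0.73 that became −0.21. The liver call ended without fish oil air 5 (0.0558). The lymphocyte call ended without normal air 4 (0.0520), fish oil air 4 (0.0596) or fish oil air 5 (0.0628), and the vascular call without normal air 2, 4 or 6 or fish oil air 3, 4 or 5 (highest 0.0988). The erythrocyte index as a covariate also ended the vascular call (0.0534), as did leaving out both replicates 3 of fish oil (0.0567), and the implied read total the lymphocyte call (0.0804).

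In ozone, fish oil changed 31 miRNAs, 17 higher and 14 lower. MiR-199a-3p rose by 1.5 (SE 0.30, edgeR adjusted p = 0.00103, higher in 5 of 5), from 4561 ± 817 (n = 6) to 12943 ± 6943 CPM (n = 5), and miR-143-3p rose by 1.27 (SE 0.34, edgeR adjusted p = 0.00945, higher in 5 of 5). MiR-191a-5p fell by 1.77 (SE 0.32, edgeR adjusted p = 0.000642, lower in 5 of 5), and miR-92a-3p, the main miRNA of its oncogenic cluster in blood, fell by 1.44 (SE 0.34, edgeR adjusted p = 0.00384, lower in 5 of 5). Also raised were miR-152-3p (+1.44), miR-29c-3p (+1.54), miR-497-5p (+1.70), miR-144-5p (+1.46), miR-10b-5p (+1.58), miR-200a-3p (+1.11) and miR-218a-5p (+1.79), and miR-30a-5p (+0.89), miR-30e-5p (+0.83) and miR-27b-3p (+0.80), which were negative with the implied read total (−0.05, −0.03 and −0.17). Also lowered were miR-181d-5p (−1.32), miR-128-3p (−1.37), miR-328a-3p (−1.63), miR-92b-3p (−1.29), let-7d-3p (−1.0), miR-146b-5p (−0.83), miR-181c-5p (−1.04), miR-151-3p (−0.79), miR-326-3p (−2.02) and miR-17-5p (−0.88). Few reads underlay miR-218a-5p, miR-10b-5p, miR-144-5p and miR-326-3p, with mean counts over all libraries of 6.83 (at its main locus), 8.48, 10.3 and 7.83. Means of 79.5 ± 32.9 CPM for miR-218a-5p in normal ozone and 58.5 ± 93.4 for miR-326-3p in fish oil ozone lie within the floor of 31.8 to 129 CPM. At an unadjusted p below 0.05 there were 47 miRNAs. In camera 0 lists passed, with 5 at an unadjusted p below 0.05, and fry called 7; the vascular wall list was nearest in camera, with 2 of 6 higher and an adjusted p of 0.0514. The implied read total gave 0 higher and 46 lower.

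Fish oil ozone 3 carried much of the comparison in ozone: without it 12 miRNAs were called by edgeR, and let-7d-3p, miR-10b-5p, miR-144-5p, miR-17-5p, miR-181c-5p, miR-200a-3p, miR-218a-5p, miR-27b-3p, miR-29c-3p, miR-30e-5p, miR-326-3p, miR-497-5p and miR-92b-3p were not. MiR-200a-3p was also lost without normal ozone 1 or fish oil ozone 5, let-7d-3p without fish oil ozone 5, miR-10b-5p without normal ozone 4, and miR-17-5p without normal ozone 3 or 5 or fish oil ozone 1, 4 or 5. MiR-326-3p was lost without normal air 3, normal ozone 1, 4 or 5, or fish oil ozone 1, 4 or 5. Across the 136 miRNAs the fish oil effects under air and ozone, which share no library, had r = 0.731 and rho = 0.756 and the same sign for 76.5%. With the filter of 10 CPM, which lets in more miRNAs, r was 0.412. MiRNAs are not independent replicates, and 1 of 100 regroupings of diet, the real one, gave an r as large. The 8 and 31 calls share 4 miRNAs against 1.82 by chance, and 7 and 30 of them were called in the average. The interaction, which also tests whether fish oil effects differ between exposures, called 0 single miRNAs in edgeR and 3 lists in camera (liver, let-7 and epithelium), none of which passed with an estimated correlation. For miR-122-5p and miR-192-5p, which fell under air and stood at +0.01 and −0.16 under ozone, its adjusted p was 0.532 over all miRNAs tested, and both passed adjusted over the list alone.

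**Figure D3:**
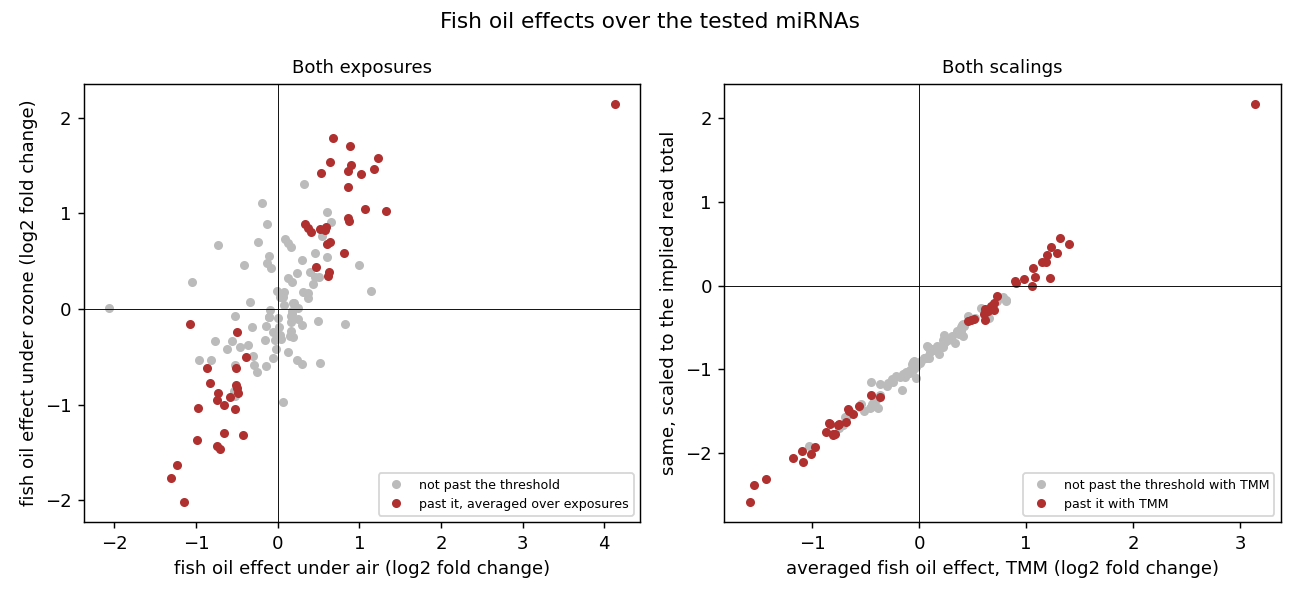
Fish oil effects (log2 fold change) of the 136 miRNAs tested: left, under air (horizontal) against under ozone (vertical), with red points past the threshold for the average; right, the averaged effect with TMM scaling (horizontal) against the implied read total (vertical). The left panel has r = 0.731, and on the right the median lies at −0.87 on the vertical axis.

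On the normal diet, ozone changed 0 of the 136 miRNAs in edgeR; 4 had an unadjusted p below 0.05. The smallest p was for miR-22-3p, a broadly expressed miRNA of heart, muscle and red cells, at −0.77 (SE 0.23, edgeR adjusted p = 0.184, lower in 6 of 6): 58286 ± 19823 CPM in air and 34231 ± 5592 in ozone (n = 6 each). DESeq2 called this 1 miRNA (−0.79, adjusted p = 0.00611) and voom called 0; without normal air 3 edgeR called it as well (−0.90, adjusted p = 0.0364). MiR-375-3p, made by endocrine cells of pancreas, gut and lung, stood at +1.0 (SE 0.31, edgeR adjusted p = 0.184, higher in 5 of 6), followed by let-7f-5p (+0.54), miR-30e-3p (+0.48) and miR-3557-5p (−0.47), none of which passed. The 95% confidence interval of a change reached 1.54-fold to either side at the median. The let-7 family lay above the other miRNAs (camera adjusted p = 0.0016, 0.712 with an estimated correlation, 0.883 in fry), with 8 of 9 members positive, 0 past the threshold in edgeR over all or over the list alone, and a median of +0.35.

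On fish oil, ozone again changed 0 miRNAs in edgeR, with 10 at an unadjusted p below 0.05; DESeq2 and voom each called 0. The smallest p values were those of the epithelial miR-200a-3p (+0.84, SE 0.33) and miR-429 (+1.34, SE 0.61), miR-375-3p (+0.81, SE 0.33, higher in 4 of 5), let-7i-5p (−0.52) and miR-181d-5p (−0.59), each with an edgeR adjusted p of 0.652. MiR-429 had few reads (mean count 7.48). In camera 3 lists passed, and 0 did with an estimated correlation. The miR-17-92 list lay lower (camera adjusted p = 0.00877, 0.364 with an estimated correlation; median −0.31; 9 of 10 negative), but not without fish oil air 3 (0.120), fish oil ozone 1 (0.0838) or fish oil ozone 3 (0.131), nor without both replicates 3 of fish oil (0.640). Liver miRNAs lay higher (camera adjusted p = 0.0437, 0.364 with an estimated correlation; median +0.65), but not without fish oil air 5 or 6 or fish oil ozone 1, 3, 5 or 6 (highest 0.215); without both replicates 3 of fish oil it passed (0.0248). The miR-30 list lay higher (camera adjusted p = 0.0493, 0.411 with an estimated correlation; 6 of 6 positive, median +0.26), but not without normal air 1, normal ozone 5, fish oil air 2, 3, 5 or 6, or fish oil ozone 1, 3 or 5 (highest 0.177), nor with total count scaling (0.0632), the implied read total (0.133) or a filter of 10 CPM (0.136), nor without both replicates 3 of fish oil (0.0688).

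Averaged over diets, ozone raised 1 miRNA, miR-375-3p (chromosome 9, 81930305 to 81930327), by 0.90 (SE 0.23, edgeR adjusted p = 0.0467, higher in 9 of 11). Its level was 1261 ± 361 CPM in air and 2523 ± 1127 in ozone on the normal diet (n = 6 each), and 1012 ± 418 (n = 6) and 1792 ± 582 (n = 5) on fish oil. Most alternatives did not call it. In edgeR the adjusted p was 0.0645 with RLE factors, 0.158 with total count, 0.173 at 10 CPM and 0.111 with the erythrocyte index as a covariate. It was 0.673 with the implied read total, 0.144 without the 5 most abundant and 0.329 without both replicates 3 of fish oil. In voom it was 0.146, and in limma on the authors' RPM 0.494. DESeq2 (0.0185), no filter (0.0171) and thinned libraries (0.0378) called it. Its log2 change was 0.78 to 1.13 over all these alternatives. Of the fits that left out 1 library, it was called only without normal air 3, normal ozone 3, normal ozone 5, fish oil air 6 or fish oil ozone 6, and its highest edgeR adjusted p was 0.215, without fish oil air 1. The next smallest p values, none of them past the threshold, were those of miR-126a-5p (+0.51), miR-30a-3p (+0.52), miR-30e-3p (+0.39) and miR-22-3p (−0.33). The miR-17-92 list lay lower and the miR-30 list higher (both camera adjusted p = 0.0221, 0.559 with an estimated correlation; medians −0.15 and +0.17). The first call ended without normal air 1 (0.0564), normal ozone 4 (0.0962), fish oil air 3 (0.215) or fish oil ozone 1 (0.0801) or 3 (0.193), and the other without normal air 1, normal ozone 2, fish oil air 2 or fish oil ozone 1, 3 or 5 (highest 0.0809). With the implied read total both stood at 0.0549, and with a filter of 10 CPM at 0.0523 and 0.0566; without both replicates 3 of fish oil the miR-17-92 list stood at 0.545.

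Whether diet altered the response to ozone was tested by the interaction, which gave 0 miRNAs past the threshold in edgeR, DESeq2 and voom, and 6 at an unadjusted p below 0.05. Liver miRNAs differed most as a list, by +1.33 at the median (camera adjusted p = 0.00342, 0.156 with an estimated correlation, 0.248 in fry). Their median ozone effect was −0.68 on the normal diet, where the list did not pass (camera adjusted p = 0.185), and +0.65 on fish oil. In 17 of 100 splits of the samples some list had a camera p as small. MiR-122-5p was at 34874 ± 27651 CPM in air and 20665 ± 11332 in ozone on the normal diet (n = 6 each), and at 8370 ± 5222 (n = 6) and 20837 ± 18096 (n = 5) on fish oil. In the last group fish oil ozone 5 had 52962 CPM and the others 10418 to 16061. The interaction of miR-122-5p was +2.07 (SE 0.85) and that of miR-192-5p +0.92 (SE 0.38), both with an edgeR adjusted p of 0.532. Without fish oil ozone 5 that of miR-122-5p was +1.35 and both had an edgeR adjusted p of 0.927. Adjusted over the list alone, with all libraries, 2 of the 3 were higher. The single miRNAs with the smallest p were let-7i-5p (−0.87), miR-200a-3p (+1.29), miR-22-3p (+0.88) and miR-181d-5p (−0.90), each at an edgeR adjusted p of 0.459, and miR-192-5p.

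The let-7 family differed between diets in the other direction, with all 9 members negative and a median of −0.41 (camera adjusted p = 0.0156, 0.518 with an estimated correlation). Epithelial miRNAs differed by +0.66 at the median (camera adjusted p = 0.0156, 0.501 with an estimated correlation), with 1 of 6 higher adjusted over the list alone and 0 over all miRNAs tested. The epithelial call ended without normal air 3, normal ozone 1, 3 or 6, fish oil air 1, or fish oil ozone 4 or 5 (highest 0.152), and without both replicates 3 of fish oil (0.0707), and those of liver and let-7 held in every fit without 1 library. Across miRNAs, which are not independent replicates, the ozone effects on both diets had r = −0.063 and rho = −0.034, with the same sign for 50%, and 62 of 100 regroupings of exposure gave an r as large.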

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

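The counts of miRNAs over other splits of the samples, the count of splits over all lists and the test of the implied read total were chosen only after the results were seen; the other tests here were written before the result each one measures. For each comparison 100 splits of the samples were counted, the real one included. Only the real split gave as many calls for fish oil averaged over exposures (real 50, highest other 11). The same held for fish oil under air (real 8, highest other 1) and under ozone (real 31, highest other 11). This argues against chance, although 1 of 100 is the smallest share that 100 splits can give. Under air the calls fell to 3 without fish oil air 4 or 5. Chance is left open for ozone averaged over diets (5 of 100, real 1, highest other 5). With 0 real calls all 100 splits gave as many for ozone on the normal diet (highest other 3), ozone on fish oil (highest other 4) and the interaction (highest other 5).

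The 50 fish oil differences averaged over exposures were set against 3 technical sources. Thinning every library to the smallest total gave a slope of 0.992 ± 0.0197 (SE) on the original log2 changes, with 50 of 50 signs kept. Thinning keeps the make-up of each library, so this shows only that unequal counts alone did not make the differences. It cannot test a bias that came with a low miRNA yield. The erythrocyte index as a covariate gave 0.982 ± 0.0103, also with 50 of 50 signs kept. That index differed little between diets (+0.39, permutation p = 0.287). The covariate could therefore take little from the diet effects, and red cell miRNA is left open. MiR-144-5p and miR-144-3p, neighbours of miR-451-5p on chromosome 10, rose by 1.32 and 0.98. MiR-451-5p itself did not pass (+0.58, edgeR adjusted p = 0.211), and other members of the erythrocyte list fell. Counting library size without the 5 most abundant miRNAs kept 42 of the 47 calls outside those 5, a share of 0.894 (26 of 26 raised, 16 of 21 lowered). Those 5 together took similar shares of the counts on both diets (−0.906 points on fish oil averaged over exposures, permutation p = 0.532). Leaving them out could therefore change little between diets, and whether a few miRNAs set the rest is left open. A batch that followed the blocks of animal numbers cannot be told apart from the groups, and a change in the tissues that release miRNA to serum remains open as a hypothesis.

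The lower miRNA share of the implied read total on fish oil had a log2 difference of −0.973 averaged over exposures. Without the 5 most abundant miRNAs it was −0.947 (permutation p = 0.00084), which argues against those 5 as its source. The log2 share is the log2 miRNA total minus the log2 implied read total, which differed by −0.865 and by 0.108 (SE 0.235). Most of the difference in share thus lay in the smaller miRNA totals of these libraries. This divides the same numbers and does not test a cause, and the SE leaves room for a part from larger libraries. Less miRNA in serum and more of other RNA in the input could each give −0.973, and no spike-in was analysed here to decide between them; an effect of the diet stays possible and untested.

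Liver miRNAs differed between diets in their response to ozone by a median of 1.33 (−0.68 on the normal diet, +0.65 on fish oil), by a test of the interaction. Leaving out each library gave a lowest median of 1.13, without normal ozone 1. With 3 members tested, the full median is the value of miR-194-5p, which had few reads (mean counts of 4.96 and 5.43 at its loci). The test therefore cannot decide whether 1 library set the values of miR-122-5p and miR-192-5p. For both of these, fish oil ozone 5 lay far above its group, at 52962 and 109257 CPM. The median was 1.18 with the implied read total and 0.81 with the authors' RPM, so scaling as part of the source is left open. The camera adjusted p was 0.156 with an estimated correlation, so the list did not pass there. In 3 of 100 splits, the real one included, the median was as large in size (highest other 1.35), but this does not allow for the choice of this list among those tested. Over all lists, 17 of 100 splits gave some list a camera p as small as the real 0.000244 (smallest of the others 2.76e-07), so chance is not excluded, nor is a diet effect on liver miRNA. By the same kind of test the epithelium list differed by 0.66 (−0.19 and +0.46; −0.19 became +0.03 with the implied read total) and the let-7 list by −0.41 (+0.35 and −0.10; −0.10 became +0.17). Neither passed with an estimated correlation in camera (adjusted p = 0.501 and 0.518).

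A sample lay far from the others of its group in 33 of 324 groups tested, against 16.2 by chance at 1 in 20. Among library values these were 158 miRNAs detected in fish oil ozone 4 (others 134 to 138) and a miR-143-3p share of 22% in normal air 4 (8.22 to 11.8%), which also had 271247 CPM of miR-143-3p, 40183 of miR-30a-5p and 108 of miR-326-3p. Muscle miRNAs were high in normal air 1 (miR-1-3p 1900, miR-133a-3p 666 and miR-206-3p 1136 CPM) and in fish oil air 2 (miR-133a-3p 1022 and miR-206-3p 1132 CPM). Fish oil ozone 5 was high in liver miRNAs, with miR-122-5p at 52962 CPM (others 10418 to 16061) and miR-192-5p at 109257 (others 50293 to 57679). Fish oil air 3 had low miR-103-3p (5506 CPM) and high miR-19b-3p (12224), miR-223-3p (2203) and miR-23a-3p (4983). Normal ozone 6 was high in miR-126a-5p (28465 CPM), miR-223-3p (5227), miR-23a-3p (4480), miR-27b-3p (8468) and miR-363-3p (820). Fish oil ozone 3 was high in miR-142-5p (5423 CPM), miR-144-5p (559) and miR-29a-3p (7230), and fish oil ozone 4 in miR-146b-5p (8326) and miR-363-3p (318). Normal ozone 5 was high in miR-185-5p (489 CPM) and miR-217-5p (489), and normal ozone 1 in miR-25-3p (31435). Low values were miR-103-3p in normal air 3 (6456 CPM), miR-128-3p in fish oil air 4 (7256) and let-7g-5p in fish oil ozone 1 (5247), and miR-141-3p was high in fish oil air 6 (1269).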

How the results depend on the processing

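The alternatives chosen after seeing the data were the implied read total as library size, library size without the 5 most abundant miRNAs, the share of the most abundant miRNA of each library, the pair of fish oil libraries left out (fish oil air 3 and fish oil ozone 3), thinned libraries for the tests of single miRNAs, and every alternative for the miRNA share. No paired analysis was possible because the animal numbers pair no rats. Of 76 named differences past the threshold, the number kept was 76 with DESeq2, 74 with RLE factors, 73 with the erythrocyte index as covariate, 72 with voom, 69 without the top 5, 66 with no filter or thinned, 64 with total count, 63 without the pair, 62 at 10 CPM, 40 with the implied read total, 39 with the authors' RPM, and 26 of 28 with only the groups compared. The rule named 8 calls under air and 24 under ozone. Those without a value in that last setting, such as miR-217-5p under air, are not among the 28. In every alternative, leaving out 1 library included, 22 passed. Only the implied read total (14 of 76) and RPM (13) turned any of them. Of 124 named values not past it, 58 changed sign in some setting without passing. Where no reason is stated below, the cause was not tested.

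Among named miRNAs past the threshold on either scale, averaged fish oil effects with the opposite sign were, with the implied read total, let-7c-5p −0.87, let-7f-5p −0.81, miR-103-3p −0.64, miR-126a-3p −0.0022, miR-126a-5p −0.30, miR-16-5p −0.87, miR-181a-5p −0.39, miR-181b-5p −0.42, miR-203a-3p −0.13, miR-22-3p −0.90, miR-221-3p −0.42, miR-23b-3p −0.29, miR-27b-3p −0.34, miR-29a-3p −0.24, miR-30a-5p −0.28, miR-30e-5p −0.21 and miR-3557-5p −0.76. With RPM, let-7f-5p and miR-3557-5p left aside, they were let-7c-5p −0.86, miR-103-3p −0.64, miR-126a-5p −0.22, miR-142-5p −0.87, miR-16-5p −0.80, miR-181a-5p −0.42, miR-181b-5p −0.34, miR-203a-3p −0.20, miR-22-3p −0.83, miR-221-3p −0.40, miR-23b-3p −0.14, miR-27b-3p −0.24, miR-29a-3p −0.15, miR-30a-5p −0.25 and miR-30e-5p −0.17. Under ozone miR-27b-3p, miR-30a-5p and miR-30e-5p turned to −0.17, −0.053 and −0.032 with the implied read total and to −0.092, −0.057 and −0.12 with RPM. Both divide by a total of which miRNAs were a smaller part on fish oil, which by construction moves every fish oil effect down.

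The number of miRNAs called under air (8 in the report) was 15 with DESeq2, 31 with voom, 38 with the implied read total, 32 with RPM, 15 without the top 5 and 14 with total count. Under ozone (31) it was 50 with RPM and 19 without the pair. For ozone averaged over diets (1) it was 0 at 10 CPM, with the covariate, the implied read total, RPM, voom, RLE factors, total count, without the top 5 and without the pair; for ozone on the normal diet (0) DESeq2 called 1. Lists past the threshold became 0 with an estimated correlation for every comparison that had any (ozone on either diet, fish oil under air, both averages and the interaction). With fry they became 7 for fish oil averaged (1) and 7 under ozone (0), and 0 for the interaction, ozone averaged and ozone on either diet. For fish oil under ozone they became 4 at 10 CPM, 1 with the implied read total, 1 with total count and 1 without the pair. For ozone averaged (2) they became 0 at 10 CPM, 0 with the implied read total and 1 without the pair; for ozone on fish oil (3), 1 without the pair; for fish oil averaged, 0 with the covariate and 2 without the pair. The 10 CPM filter tests more miRNAs, and r between fish oil effects was 0.412 with it.

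The fall in miRNAs detected on fish oil, averaged, was −16.8 at 1 count or more (permutation p = 0.0719) and turned to +9.18 after thinning (p = 0.00429), so it followed the smaller totals. The share of the 5 most abundant together differed by −0.906 points averaged, −3.14 under air and +1.33 under ozone, against rises of miR-143-3p alone, since miR-191a-5p, which fell, is also among the 5; the share of whichever miRNA led in a library differed by 3.08, 1.87 and 4.29, none past the threshold, as miR-191a-5p led in all 12 normal diet libraries. Without the top 5 the miRNA share under air was −0.92 (exact permutation, adjusted p = 0.0519).

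Leaving out 1 library at a time, the number of miRNAs called was 0 to 1 for ozone on the normal diet, 0 for ozone on fish oil and the interaction, 3 to 15 and 12 to 34 for fish oil under air and ozone, 0 to 1 for ozone averaged and 43 to 56 for fish oil averaged. Lists were 1 to 3, 0 to 4, 0 to 3, 0 to 2, 2 to 4, 0 to 2 and 0 to 2 for ozone on the normal diet, ozone on fish oil, fish oil under air, fish oil under ozone, the interaction, ozone averaged and fish oil averaged. Log2 library totals differed by −0.96 to −0.72 under air and −1.06 to −0.76 under ozone, the miR-143-3p share by 10.6 to 14.7 and 15 to 18.3 points, and the log2 miRNA share by −1.13 to −0.84 and −1.10 to −0.73. The interval of a change reached 1.89-fold at the median for the interaction and 1.37-fold for the averages. Thinning left 44 calls for fish oil averaged against 50. Depth sets a floor of 31.8 to 129 CPM.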

Other observations

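No hypothesis was tested in this part, and the pair of libraries named last was singled out only after the data were seen. The miRNA totals of 23279 to 94264 counts leave most miRNAs in the table untested: 454 of 753 names had any count and 136 could be tested. Of the names in the Dlk1-Dio3 list, a large imprinted cluster expressed in brain and fetal tissue, none had more than 17 counts in a library. Replicates of a group had r from 0.859 to 0.981 over 55 pairs, across miRNAs, which are not independent replicates. On principal components of log2 CPM, which held 31.1% and 14.8% of the variance, fish oil air 3 and fish oil ozone 3 stood apart from the other libraries.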
